A study of Homo sapiens with 27 samples.

How the data were processed

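Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out for 3 histone marks in 3 human neuroblastoma cell lines. H3K4me3 marks promoters, H3K27ac marks active promoters and enhancers, and H3K27me3 is the mark of Polycomb repression. The labels name SH-SY5Y as adrenergic, and they name SH-EP and a ceritinib-resistant derivative of SH-SY5Y, grown in 1.5 µM ceritinib, as mesenchymal. Ceritinib (LDK378) is an ALK inhibitor. The derivative is called SH-SY5Y-LDK-resistant, or the resistant line, below. Of 27 samples in the labels, 18 were ChIP samples, 2 for each line and mark, and 9 were inputs.

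Tools named in the submitters' processing notes were Bowtie2 3.4.3 (the version as listed there), SAMtools 1.9, Picard and MACS2 2.1.1, with the builds hg19 and GRCh37. Settings of the peak caller, and how the 2 ChIP samples of a group entered it, are not given in the sources used here. One peak list per line and mark was used, 9 in all, so the lists have no replicate error and their sequencing depth is unknown. Each peak in the lists deposited by the authors carries a score, a fold enrichment (a ratio of ChIP to background), a −log10 p-value and a −log10 q-value. These values are the authors' own, and they were used to describe, rank or filter peaks within a list. H3K4me3 and H3K27ac lists were in narrow-peak format and H3K27me3 lists in broad-peak format. The lowest −log10 q in any list lay between 2.00 and 2.03. Numbers missing from the running peak names came to between 113 and 240 in the H3K4me3 and H3K27me3 lists and to 0 in the H3K27ac lists.

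Peaks on chromosomes 1 to 22 and X were compared, which left out between 0.570% and 3.66% of the peaks of a list. Coordinates are those of the files (hg19), counted from 1. The Jaccard index of 2 lists is the length covered by both divided by the length covered by either. The share of peaks of one list overlapped by at least 1 bp in another was set beside the mean of 20 random placements of the peaks on the same chromosomes.

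An annotation of hg19 was not used here, and the reference table of gene names belongs to another assembly. The comparisons of promoters, the gene lists, the states of promoters and the distances to transcription start sites, which had been fixed before the data were examined, were therefore not run, and genes are not named. In their place the genome was divided into windows of 2 kb, the width of the planned promoter window. A window carried a mark when peaks covered at least 200 bp of it. A window was counted as gained when it carried the mark in the first line and not in the reference, and as lost in the opposite case. Gained minus lost is thus the difference in marked windows between the lists, and its sign depends on their size. Windows were called active (H3K4me3 and H3K27ac without H3K27me3), bivalent (H3K4me3 and H3K27me3), repressed (H3K27me3 alone), acetylated alone or marked by H3K4me3 alone. This window scheme was chosen after the data had been seen.

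Windows shared by 2 lines and missing in the third were counted with each line as the odd one out. Beside them stands the product of both lines' gains (or losses) divided by the number of eligible windows, which for gains include windows that no list covers. No simulation of unchanged lines was made, since each line had 1 list. Both comparisons with SH-SY5Y share its list, so part of any excess may come from that list.

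Regions were named by the rule fixed for genes, applied to tiles of 20 kb: the 8 tiles per direction with the largest difference in H3K27ac covered length among those in which all 3 marks moved one way, and the 5 H3K27ac domains of each line with the longest covered length of such peaks as define them. The text may name fewer. For domains, H3K27ac peaks over 2.5 kb from an H3K4me3 peak of the same line, in place of a start site, were merged when within 12.5 kb, and the 5% with the longest covered length were called large. The 5 longest H3K27me3 peaks per line and H3K4me3 peaks of at least 5 kb were added after the data had been seen, as was a chromosome 6 interval from 29 to 33 Mb.

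Alternatives were a −log10 q of at least 5, a fold of at least 4, the same number of peaks or the same covered length per mark, a minimum overlap of 1 bp or 1000 bp, and windows of 5 kb. Overlaps were recomputed with a reciprocal overlap of 50%, and domains with a merging distance of 5 kb, ranking by fold times width, and no peak left out. Every comparison is a description without a test or p-value. Intervals of 95% for 4 values of the closing section come from leaving out each of the 23 chromosomes in turn and cover the spread between chromosomes only. The interval functions were tested on 3 simulated pairs of lists of 5000 peaks with known overlap, which they recovered with a largest error in the Jaccard index of 0, and against bedtools. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, matplotlib 3.10.9 and bedtools 2.31.1 were used.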

Results

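Genome-wide occupancy of H3K4me3, H3K27ac and H3K27me3 was profiled in SH-SY5Y, an adrenergic neuroblastoma line, in its ceritinib-resistant derivative and in SH-EP, both named mesenchymal in the labels. One peak list stood for each line and mark, so no value below has a replicate error, and depth is unknown. On chromosomes 1 to 22 and X, H3K4me3 peaks numbered 31285 in SH-SY5Y, 41165 in the resistant line and 64518 in SH-EP, and covered 38.3, 43.3 and 50.9 Mb. H3K27ac peaks numbered 105399, 117633 and 102387 in the same order and covered 71.1, 77.7 and 66.5 Mb. H3K27me3 peaks numbered 185171, 221901 and 181120 and covered 428, 397 and 405 Mb. The median fold enrichment given by the authors for H3K4me3 was 23.1 in SH-SY5Y, 10.3 in the resistant line and 7.68 in SH-EP.

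The first question was which marked regions the lines share. By H3K27ac the resistant line lay nearer to SH-EP than to its parent: the Jaccard index was 0.416 with SH-EP and 0.282 with SH-SY5Y, and SH-EP and SH-SY5Y shared least, at 0.228. By H3K4me3 the order was the other way, with 0.685 between the resistant line and SH-SY5Y, 0.564 between the resistant line and SH-EP, and 0.487 between SH-EP and SH-SY5Y. Counted in windows, the resistant line was nearer to SH-EP than to SH-SY5Y on 23 of 23 chromosomes by H3K27ac and on 0 of 23 by H3K4me3. For H3K27me3 the index was 0.385 with SH-EP and 0.341 with SH-SY5Y, and the resistant line was nearer to SH-EP on 19 of 23 chromosomes. That order turned among stronger H3K27me3 peaks: at a −log10 q of at least 5 the indices were 0.232 with SH-EP and 0.325 with SH-SY5Y, and at a fold of at least 4 they were 0.107 and 0.272.

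**Figure D1:**
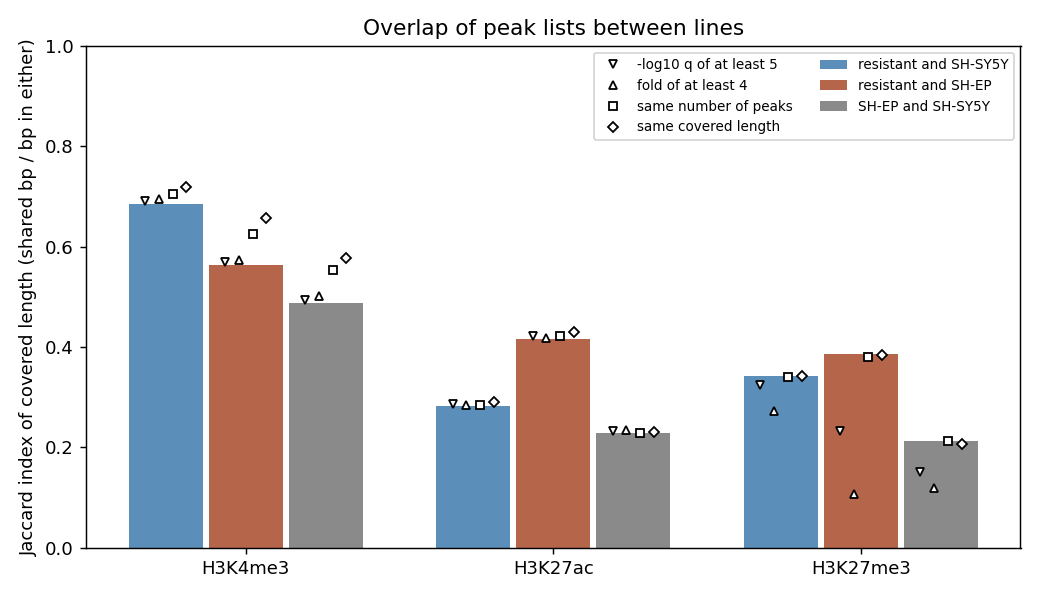
Bars give the Jaccard index of covered length (y axis, 0 to 1) for each pair of lines and mark as deposited, and open symbols give it under 4 filters of the peaks. The resistant line overlaps SH-EP (0.416) more than SH-SY5Y (0.282) by H3K27ac, and SH-SY5Y (0.685) more than SH-EP (0.564) by H3K4me3.

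Of the H3K27ac peaks of the resistant line, 47.9% were overlapped in SH-EP and 36.9% in SH-SY5Y, where random placement gave 3.95% and 4.16%. For H3K4me3, 72.9% of resistant-line peaks were overlapped in SH-EP and 60.0% in SH-SY5Y, against 3.8% and 2.43% at random. This order turned with lists of the same covered length, where 78.7% of its H3K4me3 peaks were overlapped in SH-EP and 87.4% in SH-SY5Y. For H3K27me3 the shares were 51.7% and 51.8%, against 19.1% and 20.9% at random.

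Differences in H3K27ac lay mainly away from H3K4me3. In windows with H3K4me3 in any line, the Jaccard index of H3K27ac windows was 0.670 between the resistant line and SH-EP, 0.614 between the resistant line and SH-SY5Y, and 0.50 between SH-EP and SH-SY5Y. In windows without H3K4me3 in any line it was 0.279, 0.148 and 0.0885. Sites of this second kind hold distal enhancers among others.

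The comparison of SH-EP with SH-SY5Y sets the mesenchymal line against the adrenergic one. SH-EP carried H3K27ac in 43599 windows that lacked it in SH-SY5Y and lacked it in 47534 windows that carried it there, with 30312 in common. For H3K4me3, 31936 windows were gained and 8810 lost, and for H3K27me3, 179495 were gained and 194371 lost. With lists of the same covered length H3K4me3 was gained in 10909 windows and lost in 10716. The balance of the other marks turned in those lists, with 44848 gained and 42058 lost for H3K27ac and 182647 gained and 168911 lost for H3K27me3. All 3 marks moved toward the active side in 1565 tiles of 20 kb and toward the repressed side in 889. A mark counted as present in a tile when peaks covered at least 200 bp of it. Tiles were not recomputed at equal covered length, so this excess cannot be told apart from the longer H3K4me3 list of SH-EP. The leading tile on the active side lay on chromosome 7 from 27140001 to 27160000: H3K27me3 covered 20 kb of it in SH-SY5Y and in the resistant line and 0 kb in SH-EP, where H3K27ac covered 18.6 kb and H3K4me3 16.5 kb. On chromosome 5, the tile from 33300001 to 33320000 had 17.9 kb of H3K27ac in SH-EP and 14.6 kb of H3K27me3 in SH-SY5Y. On chromosome 20, the tile from 23120001 to 23140000 had 15.1 kb of H3K27ac in SH-EP, 10.3 kb in the resistant line and 0 kb in SH-SY5Y, whose H3K27me3 covered 18.8 kb. Opposite to these, the tile on chromosome 12 from 110160001 to 110180000 had 19.7 kb of H3K27ac in SH-SY5Y and 0 kb in both other lines, where H3K27me3 covered 4.48 kb in SH-EP and 4.28 kb in the resistant line. On chromosome 17, the tile from 64960001 to 64980000 had 19.1 kb of H3K27ac in SH-SY5Y and 19.4 kb of H3K27me3 in SH-EP. The tile on chromosome 16 from 55680001 to 55700000 had 16.0 kb of H3K27ac and 9.61 kb of H3K4me3 in SH-SY5Y, while H3K27me3 covered 17.8 kb in SH-EP and 8.24 kb in the resistant line.

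The resistant line was compared with its parent to ask what differs between them. All its samples were grown in 1.5 µM ceritinib and those of SH-SY5Y were not. Effects of selection and of the drug being present therefore cannot be told apart. H3K27ac was gained in 44833 windows and lost in 39340, with 38506 kept. H3K4me3 was gained in 11098 windows and lost in 5061, with 31847 kept, and H3K27me3 was gained in 138342 windows and lost in 142682. All 3 balances, each the difference in marked windows between the lists, turned at equal covered length and so give no direction of change. There H3K27ac was gained in 33818 windows and lost in 37285, H3K4me3 in 4936 and 6932, and H3K27me3 in 150958 and 114980. All 3 marks moved toward the active side in 282 tiles and toward the repressed side in 396. Of the 8 leading tiles on the active side, 4 lay on chromosome 12 between 65980001 and 66300000. In the first of these, from 66020001 to 66040000, H3K27me3 covered 19.1 kb in SH-SY5Y and 0 kb in the resistant line, where H3K27ac covered 15.7 kb. Its H3K27ac covered 10.8 kb in SH-EP. On chromosome 6, the tile from 130000001 to 130020000 had 14.7 kb of H3K27ac in the resistant line, 8.81 kb in SH-EP, and 16.5 kb of H3K27me3 in SH-SY5Y. Toward the repressed side, the tile on chromosome 10 from 43580001 to 43600000 had 16.9 kb of H3K27ac in SH-SY5Y and 8.28 kb of H3K27me3 in the resistant line. The tile on chromosome 3 from 128180001 to 128200000 had 14.8 kb of H3K27ac in SH-SY5Y, and H3K27me3 covered 10.8 kb in each of the other lines. On chromosome 15, the tile from 74580001 to 74600000 had 19.5 kb of H3K27ac in SH-SY5Y, against 8.30 kb of H3K27me3 in the resistant line and 3.60 kb in SH-EP.

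Between the lines named mesenchymal, SH-EP carried H3K27ac in 25434 windows without it in the resistant line and lacked it in 34862 windows that had it there, with 48477 in common. H3K4me3 was gained in 25761 windows and lost in 8672, and H3K27me3 was gained in 112627 and lost in 123163. At equal covered length H3K4me3 was gained in 8985 windows and lost in 6796, and H3K27ac turned to 29227 gained and 22970 lost. For H3K27me3 the balance turned with the same number of peaks and among stronger peaks. Tiles with all 3 marks toward the active side in SH-EP numbered 901, and 222 moved the other way. Here too the H3K4me3 list of SH-EP was the longer one, and tiles were not recomputed at equal covered length. On chromosome 7, the tile from 27160001 to 27180000, beside the leading tile of the comparison with SH-SY5Y, had 20 kb of H3K27me3 in both SH-SY5Y and the resistant line and 8.57 kb of H3K27ac in SH-EP. On chromosome 17, the tile from 46640001 to 46660000 had 20 kb of H3K27me3 in SH-SY5Y and in the resistant line, and 9.57 kb of H3K27ac with 10.6 kb of H3K4me3 in SH-EP. On chromosome 21, the tile from 47160001 to 47180000 had 8.21 kb of H3K27ac in the resistant line and 10.2 kb of H3K27me3 in SH-EP.

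Shared changes were counted against SH-SY5Y. H3K27ac was present in both mesenchymal lines and not in SH-SY5Y in 20495 windows, against 10524 windows missing only in SH-EP and 2330 missing only in the resistant line. Independent gains would give 1358 windows. H3K27ac of SH-SY5Y was absent from both other lines in 37010 windows, against 24022 for independent losses. The same count for H3K4me3 was 4179, against 1208 for independent losses. Windows with H3K27ac in the resistant line alone numbered 24338 and in SH-EP alone 23104. For H3K4me3 these counts were 4041 and 24879, so the H3K4me3 count does not set SH-SY5Y apart. For H3K27me3, 93588 windows were shared by the mesenchymal lines alone and 78409 were missing only in SH-EP. At a fold of at least 4 these became 953 and 8471. For H3K4me3 the counts were 7057 and 4631, and at equal covered length they were 2704 and 4564, so the order turned.

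H3K27me3 was then read in the windows where H3K27ac differed. In the 37010 windows with H3K27ac in SH-SY5Y alone, H3K27me3 was present in 2.22% in SH-SY5Y, 19.0% in the resistant line and 26.7% in SH-EP. Windows acetylated in all 3 lines carried H3K27me3 in between 1.80% and 3.09%, and windows acetylated in no line in between 21.0% and 22.3%. In the 20495 windows acetylated in both mesenchymal lines alone, H3K27me3 was present in 9.81% in SH-SY5Y, 2.45% in the resistant line and 0.820% in SH-EP, and 84.5% carried no mark in SH-SY5Y. In the 23104 windows acetylated in SH-EP alone it was present in 22% in SH-SY5Y and 20.4% in the resistant line. Where SH-SY5Y-only acetylation coincided with H3K4me3 in any line (4505 windows), H3K27me3 was present in 42.5% in the resistant line and 40% in SH-EP. Windows with H3K4me3 in any line and acetylation in none carried it in 45.7% and 36.0%. These shares depended on the threshold: at a fold of at least 4, SH-SY5Y-only acetylated windows carried H3K27me3 in 1.30% in the resistant line and 1.84% in SH-EP, against 1.35% and 1.39% of windows acetylated in no line. At that filter windows acetylated in both mesenchymal lines alone carried it in 2.14% in SH-SY5Y, against 2.25% of windows acetylated in no line. The windows acetylated in SH-EP alone then carried it in 4.65% in SH-SY5Y and 3.32% in the resistant line, above the 2.25% and 1.35% of windows acetylated in no line.

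**Figure D2:**
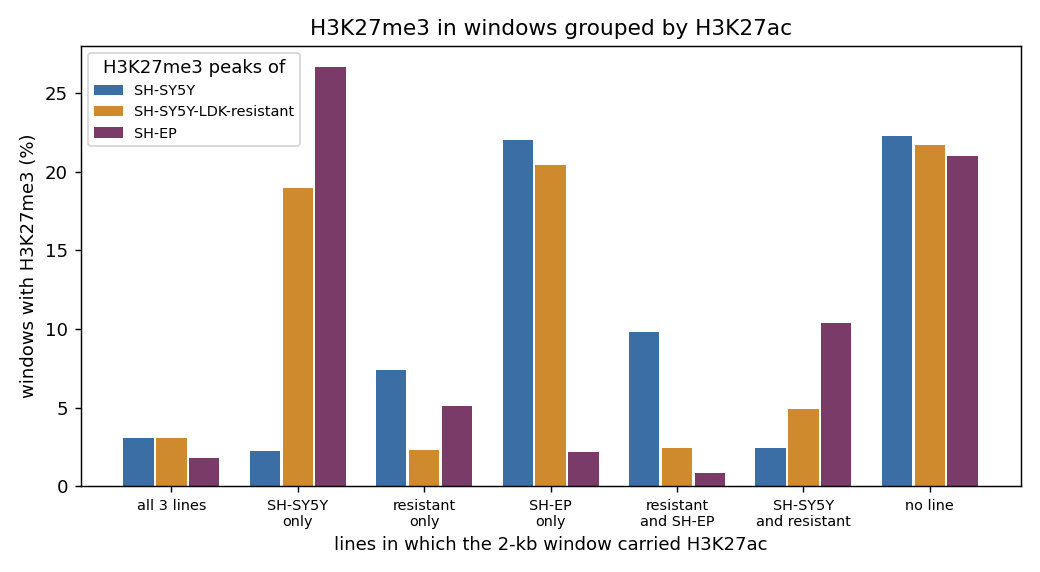
Bars give the percentage of 2-kb windows with H3K27me3 in each line (y axis), for windows grouped by the lines in which they carried H3K27ac (x axis). Windows acetylated in SH-SY5Y alone carried H3K27me3 in 2.22% in SH-SY5Y, 19.0% in the resistant line and 26.7% in SH-EP.

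Windows that went from H3K27me3 without H3K27ac to H3K27ac without H3K27me3 numbered 6727 from SH-SY5Y to SH-EP and 2982 from SH-SY5Y to the resistant line. Of these, 1565 did so in both lines, where independent events over 314613 eligible windows would give 63.8. Most of the eligible windows carried H3K27ac in no line, so an excess over this product was to be expected and its size has no reading here. Windows in the opposite direction numbered 10351, 6688 and 4721, with 913 from independent events. This balance turned when only stronger peaks were kept: at a fold of at least 4, 1341 windows went from H3K27me3 to H3K27ac and 572 the other way in SH-EP, 625 and 392 in the resistant line, and 348 and 52 in both. The H3K27me3 list of SH-SY5Y was then the longest, at 58.1 Mb, against 31.3 Mb in the resistant line and 35.3 Mb in SH-EP. At equal covered length the balance did not turn. The counts were 6288 and 9142 in SH-EP, 2244 and 6330 in the resistant line, and 1317 and 4351 in both. Those lists also held weaker peaks, and lists of strong peaks were not trimmed to equal covered length for this balance. The turn thus cannot be told apart from list length. Active windows numbered 25949 in SH-SY5Y, 30496 in the resistant line and 36881 in SH-EP, and bivalent windows 5465, 6979 and 8444. The bivalent order did not hold under most alternatives: at equal covered length the counts were 5035, 5145 and 3508, and at a fold of at least 4 they were 1799, 1611 and 625. Active windows at equal covered length numbered 25752, 24901 and 27119. Of the active windows of SH-SY5Y, 1550 were bivalent and 622 repressed in the resistant line, and 954 were bivalent and 1203 repressed in SH-EP. Of its bivalent windows, 1002 were active in the resistant line and 1299 in SH-EP, and of its 310717 repressed windows 549 and 2609 were active. An active window needs H3K4me3, which marked 60034 windows in SH-EP and 42945 in the resistant line. Transitions were not recomputed at equal covered length, so the higher counts of SH-EP cannot be told apart from its longer H3K4me3 list.

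Large H3K27ac domains numbered 1010 in SH-SY5Y, 955 in the resistant line and 689 in SH-EP. By their definition these are 5% of 20190, 19097 and 13771 domains. With no peak left out near H3K4me3 they numbered 1478, 1378 and 1379, so the low count of SH-EP depends on that rule. Of the 955 large domains of the resistant line, 27.3% overlapped a large domain of SH-EP and 21.7% one of SH-SY5Y. Domains were ranked by the length of peaks away from H3K4me3, and the lengths printed here are those of all H3K27ac peaks within the domain. The domain of SH-SY5Y ranked first lay on chromosome 5 from 168068383 to 168258707, where H3K27ac covered 85.7 kb in SH-SY5Y, 13.7 kb in the resistant line and 5.69 kb in SH-EP. On chromosome 7 from 133380806 to 133584847 it covered 77.3, 1.16 and 0.624 kb in the same order, and on chromosome 16 from 17357130 to 17504973 it covered 63.1, 4.99 and 0 kb. The first-ranked domain of the resistant line, on chromosome 10 from 80835474 to 80994244, was acetylated in all 3 lines, over 90.5, 104 and 80.3 kb. Its next domain, on chromosome 11 from 12139799 to 12262357, was covered over 2.35 kb in SH-SY5Y, 77.6 kb in the resistant line and 76.2 kb in SH-EP. On chromosome 12 from 66227798 to 66355309, a domain among the 5 ranked first in both mesenchymal lines had 73.7 kb of H3K27ac in the resistant line and 59.9 kb in SH-EP. H3K27me3 covered 120 kb of it in SH-SY5Y, 41.6 kb in the resistant line and 0 kb in SH-EP. The first-ranked domain of SH-EP, on chromosome 3 from 158417401 to 158511303, was covered over 53.4 kb in SH-EP, 7.75 kb in the resistant line and 1.59 kb in SH-SY5Y.

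**Figure D3:**
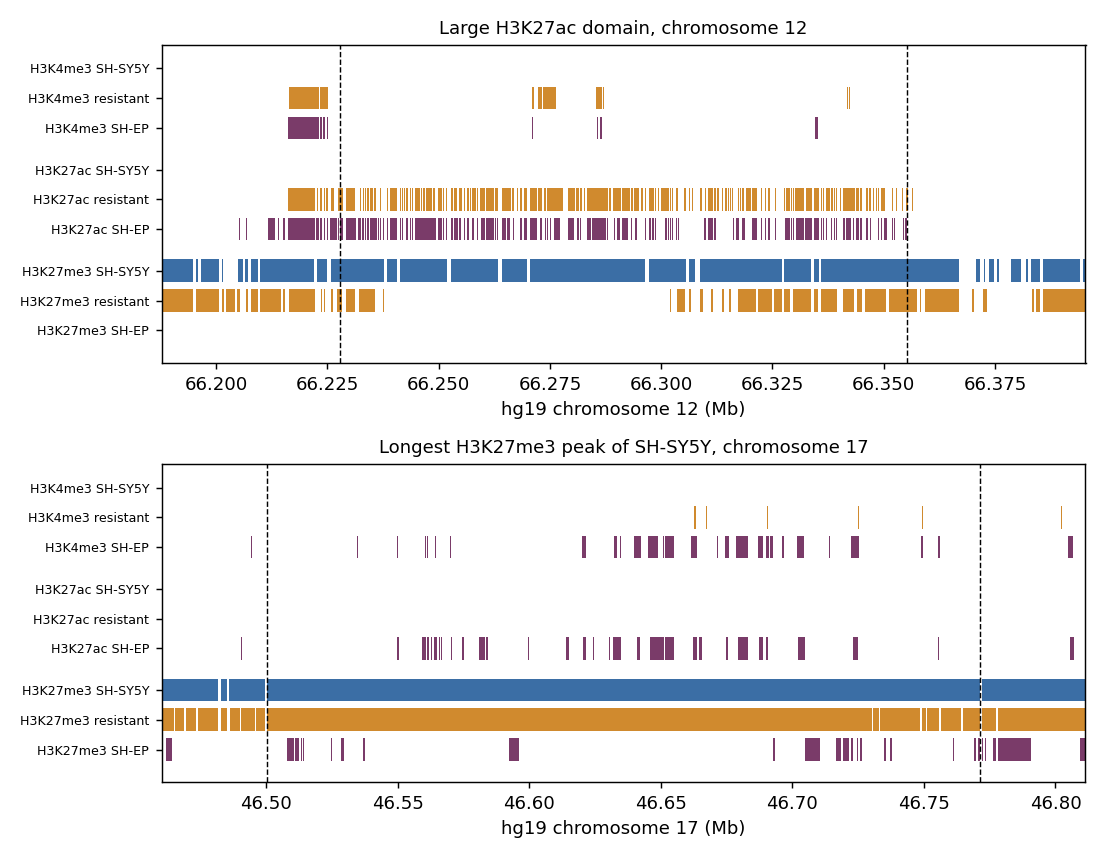
Peaks of the 9 lists (rows) are drawn to scale along hg19 coordinates in Mb, with dashed lines at the ends of the named region: above, the chromosome 12 domain, and below, the longest H3K27me3 peak of SH-SY5Y on chromosome 17. H3K27me3 covers 120 kb of the chromosome 12 domain in SH-SY5Y, 41.6 kb in the resistant line and 0 kb in SH-EP.

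The longest H3K27me3 peak of SH-SY5Y spanned 271 kb on chromosome 17 from 46500355 to 46771403. H3K27me3 covered 267 kb of it in the resistant line and 26.0 kb in SH-EP, where H3K27ac covered 41.8 kb. On chromosome 20 from 55418085 to 55653256, a peak of 235 kb in SH-SY5Y had 0.191 kb of H3K27me3 in the resistant line and 181 kb in SH-EP. The longest peak of SH-EP spanned 130 kb on chromosome 10 from 102465479 to 102595931, with 127 kb covered in the resistant line and 48.5 kb in SH-SY5Y. On chromosome 15 from 66345927 to 66467918, H3K27me3 covered 122 kb in SH-EP, 113 kb in the resistant line and 0 kb in SH-SY5Y, where H3K27ac covered 6.67 kb.

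H3K27me3 length was distributed over the chromosomes differently in the 3 lines. On chromosome 10 it covered 10.8 Mb in SH-SY5Y, 15.2 Mb in the resistant line and 19.7 Mb in SH-EP, with mean folds of 2.79, 2.93 and 2.94. On chromosome 4 it covered 27, 19.6 and 13.9 Mb, with mean folds of 2.88, 3.01 and 2.91. On chromosome X it covered 49.1, 25.3 and 29 Mb, with mean folds of 2.72, 2.87 and 2.90. H3K4me3 covered more length in both mesenchymal lines than in SH-SY5Y on all 23 chromosomes.

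**Figure D4:**
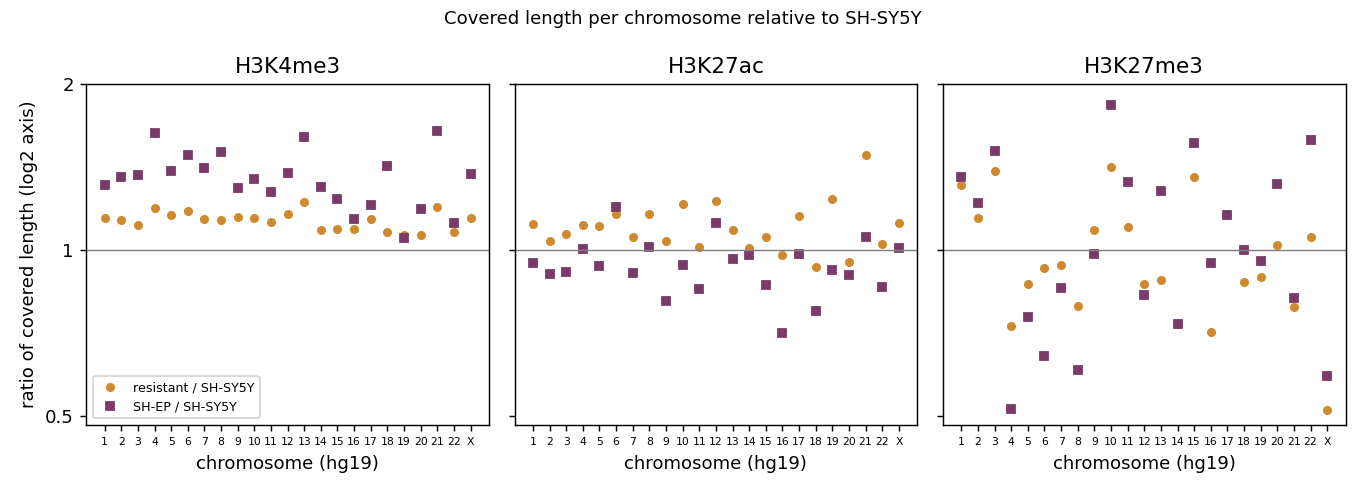
Points give the covered length of each mark per chromosome (x axis) divided by that of SH-SY5Y (y axis, log2 scale), for the resistant line (circles) and SH-EP (squares). H3K27me3 ratios spread most, from 0.515 on chromosome 4 to 1.83 on chromosome 10 in SH-EP.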

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

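The look at the haplotype contigs was chosen after the data had been seen, and no test was available for any result of this part, since each line and mark had 1 peak list.

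H3K27ac covered more length in the resistant line than in SH-SY5Y (a ratio of 1.09, from 71.1 to 77.7 Mb, with median folds of 5.0 and 5.53) and less in SH-EP (a ratio of 0.935, with 66.5 Mb and a median fold of 5.55). The lines named mesenchymal thus lay on opposite sides of SH-SY5Y in covered length, and the difference between them was not tested. At a fold of at least 4 the lengths were 61.5 Mb in SH-SY5Y, 70.8 Mb in the resistant line and 60.3 Mb in SH-EP, while SH-EP then had more peaks than SH-SY5Y (79310 and 71230) and 846 more acetylated windows.

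Peaks also lay on the haplotype contigs of chromosome 6, which were outside the comparisons and which, as background, are alternative versions of the major histocompatibility complex. H3K27ac peaks there numbered 600 in SH-SY5Y, 853 in the resistant line and 820 in SH-EP. H3K27me3 peaks numbered 551, 445 and 233, and H3K4me3 peaks 939, 1106 and 1233. Covered length was higher in SH-EP than in SH-SY5Y on 7 of 7 contigs for H3K27ac and for H3K4me3, and on 0 of 7 for H3K27me3. On chromosomes 1 to 22 and X the SH-EP list held 2.06 times as many H3K4me3 peaks as that of SH-SY5Y, so the H3K4me3 direction on the contigs does not set them apart. Chromosome 6 as a whole went the same way for the other marks. In SH-SY5Y, the resistant line and SH-EP, H3K27ac covered 3.29, 3.83 and 3.94 Mb of it. H3K27me3 covered 28.0, 25.9 and 18.0 Mb in the same order. The directions of these marks therefore do not set the contigs apart from chromosome 6. The contigs resemble each other and the chromosome, so they are not independent.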

How the results depend on the processing

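Alternatives of windows and their states, the chromosome 6 interval, the fold and covered-length filters of overlaps and the domains with no peak left out were chosen after seeing the data; the other alternatives of peak numbers, overlaps and domains were fixed before the data were examined. The alternatives planned for promoters, gene lists and promoter states were not run, for want of an annotation of hg19. No paired analysis was possible because each line and mark had 1 peak list and no test was made; for the same reason no replicate could be left out. Depth is unknown, so its effect on the number of weak peaks was not measured. Tiles, transitions between states, wide H3K4me3 peaks and the named regions were not recomputed under alternatives. By H3K27ac the resistant line overlapped SH-EP more than SH-SY5Y under every filter of the peaks tried, and by H3K4me3 less by Jaccard index under each. Unless stated, the cause of a change was not tested. Of the values that answer a comparison, 176 stayed close to the main value (within 1.5 times for counts, within the 95% binomial interval for shares and overlaps, and within a 95% counting interval for differences of counts), 112 moved and 6 reversed; of the others, 78 stayed close, 138 moved and 36 reversed. Among the moved values were 23 of windows gained, 19 of windows lost and 12 in each direction between H3K27me3 and H3K27ac.

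With peaks of a −log10 q of at least 5, H3K27me3 peaks numbered 42437 in SH-SY5Y, 36897 in the resistant line and 24135 in SH-EP, and with a fold of at least 4 they numbered 5704, 6722 and 3484. The Jaccard index of the resistant line with SH-EP minus that with SH-SY5Y reversed for H3K27me3 to -0.0926 and -0.165 under these 2 filters. With the same number of peaks it was 0.0405 for H3K27me3 and -0.0795 for H3K4me3, and with the same covered length -0.0606 for H3K4me3 and 0.139 for H3K27ac. With a reciprocal overlap of 50%, the share of resistant-line peaks overlapped in SH-EP minus that in SH-SY5Y was 5.95 points for H3K4me3 and 8.49 for H3K27ac, and for H3K27me3 it reversed to 0.842 points. For H3K4me3 this difference was 11.99 points at a −log10 q of at least 5 and 10.0 at a fold of at least 4, and it reversed to -3.33 with the same number of peaks and -8.72 with the same covered length. Under these 4 settings it was 11.6, 12.6, 12.4 and 17.2 points for H3K27ac, and -31.3, -26.3, -1.33 and, reversed, 3.20 points for H3K27me3. With no peak left out near H3K4me3, large domains of the resistant line were overlapped in SH-EP more often than in SH-SY5Y by 14.3 points.

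In the order SH-EP against SH-SY5Y, resistant line against SH-SY5Y, and SH-EP against resistant line, H3K27me3 windows gained were 65485, 35695 and 60569 at a −log10 q of at least 5, 14461, 8607 and 16186 at a fold of at least 4, and 84585, 65299 and 50776 with 5 kb windows. Those lost were 110976, 82543 and 59212, then 27521, 21728 and 16125, then 88371, 65211 and 54650. With a minimum overlap of 1000 bp the resistant line gained 90593. H3K4me3 windows gained under that overlap were 4731, 3369 and 3339, and those lost 3606, 1946 and 3637. With the same covered length the H3K4me3 gains were 10909, 4936 and 8985, and with the same number of peaks SH-EP gained 15904 against SH-SY5Y and 12188 against the resistant line. H3K27ac windows gained under a minimum of 1000 bp were 16091, 18713 and 9012, and those lost 18474, 15526 and 14582. With 5 kb windows H3K27ac gains were 28754 and 27998 against SH-SY5Y, and losses 31500, 25823 and 21909. With the same covered length SH-EP lost 22970 against the resistant line. Fewer windows are available at 5 kb by construction.

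Windows gained minus lost reversed with the same covered length to 2790 (SH-EP against SH-SY5Y), -3467 (resistant line against SH-SY5Y) and 6257 (SH-EP against resistant line) for H3K27ac, to -1996 for H3K4me3 of the resistant line, and to 13736 and 35978 for H3K27me3 of SH-EP and the resistant line against SH-SY5Y. Other reversals were 846 for H3K27ac of SH-EP against SH-SY5Y at a fold of at least 4, -298 for H3K4me3 of SH-EP against the resistant line at a minimum of 1000 bp, and 88 for H3K27me3 of the resistant line with 5 kb windows. H3K27me3 of SH-EP against the resistant line reversed to 1357 at a −log10 q of at least 5, 61 at a fold of at least 4, 18879 with the same number of peaks and 4614 at a minimum of 1000 bp.

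Windows in both mesenchymal lines and not SH-SY5Y were, for H3K4me3, 4396 with the same number of peaks, 2704 with the same covered length and 1680 at a minimum of 1000 bp. Their excess over windows missing only in SH-EP reversed under these settings to -665, -1860 and -268. For H3K27ac they were 7894 at a minimum of 1000 bp and 13645 with 5 kb windows. For H3K27me3 they were 15237 at a −log10 q of at least 5, 953 at a fold of at least 4, 57336 at a minimum of 1000 bp and 47335 with 5 kb windows. The excess reversed to -23517 and -7518 under the first pair of these.

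Windows from H3K27me3 to H3K27ac at a −log10 q of at least 5, a fold of at least 4 and a minimum of 1000 bp were 4065, 1341 and 1762 for SH-EP against SH-SY5Y, 1724, 625 and 1106 for the resistant line against SH-SY5Y, 2133, 710 and 807 for SH-EP against the resistant line, and 985, 348 and 519 for both mesenchymal lines. From H3K27ac to H3K27me3 they were 3384, 572 and 2688, then 1660, 392 and 1688, then 411, 51 and 236, and 774, 52 and 1088. The first count minus the second reversed at a −log10 q of at least 5 and a fold of at least 4 to 681 and 769 for SH-EP against SH-SY5Y, 64 and 233 for the resistant line against SH-SY5Y, and 211 and 296 for both. It reversed neither with the same number of peaks nor with the same covered length. In the chromosome 6 interval, H3K27me3 windows of the resistant line minus SH-SY5Y reversed to 3 at a −log10 q of at least 5, 1 at a fold of at least 4, 17 with the same covered length and 2 at a minimum overlap of 1 bp. Few windows were left under the q and fold filters: 5 in SH-SY5Y and 8 in the resistant line, then 0 and 1.

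Active windows at a minimum of 1000 bp numbered 10051 in SH-SY5Y, 12392 in the resistant line and 11590 in SH-EP, and the resistant line's excess over SH-SY5Y reversed to -851 with the same covered length. Bivalent windows in the same order were 3544, 3912 and 3026 at a −log10 q of at least 5, 1799, 1611 and 625 at a fold of at least 4, and 1346, 1132 and 405 at a minimum of 1000 bp. Those of SH-EP were 4662 with the same number of peaks, 3508 with the same covered length and 13194 at a minimum of 1 bp. Their excess over SH-SY5Y reversed in SH-EP to -518, -1174, -941, -785 and -1527 under the first 5 of these settings (q, fold, 1000 bp, number, length), and in the resistant line to -188 at a fold of at least 4 and -214 at 1000 bp.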

Other observations

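Written after their results or the pattern were known were the tests of acetylation at SH-EP-only H3K4me3 windows, of list length, of exchanged labels, and of H3K27me3 at a −log10 q of at least 5. The chromosome 6 interval and wide H3K4me3 peaks were also chosen after the data had been seen.

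H3K4me3 peaks of at least 5 kb numbered 201 in SH-SY5Y, 322 in the resistant line and 221 in SH-EP. Of those of SH-EP, 71.0% overlapped such a peak in the resistant line and 39.8% one in SH-SY5Y. Of those of SH-SY5Y, 63.2% overlapped one in the resistant line and 43.8% one in SH-EP. Of those of the resistant line, 48.8% overlapped one in SH-EP and 39.4% one in SH-SY5Y. Between 92.5% and 99.1% of the wide peaks of a line overlapped an H3K4me3 peak of any width in another. The lower shares thus reflect the limit of 5 kb, and they also depend on the number of wide peaks in the other line. H3K27ac and H3K27me3 without H3K4me3 met in 445 windows in SH-SY5Y, 778 in the resistant line and 384 in SH-EP. The resistant line stayed highest under every alternative. The order of SH-SY5Y and SH-EP turned under most of them: at equal covered length the counts were 269, 591 and 496.

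The interval of chromosome 6 from 29 to 33 Mb, which as background holds the major histocompatibility complex, had H3K27ac in 56 windows in SH-SY5Y, 84 in the resistant line and 92 in SH-EP, and H3K27me3 in 65, 61 and 24. At a −log10 q of at least 5 the H3K27me3 windows fell to 5, 8 and 3. At a fold of at least 4 they fell to 0, 1 and 0, so they rest mostly on weak calls. Chromosome 6 as a whole also had more H3K27ac length and less H3K27me3 length in both mesenchymal lines than in SH-SY5Y. Among intervals of 4 Mb with a similar mean number of marked windows in both lines compared, the H3K27ac ratio of this interval to SH-SY5Y stood at percentile 72.9 of 399 for the resistant line and 77.5 of 444 for SH-EP. Its H3K27me3 ratio stood at percentile 19.7 of 66 and 16.7 of 54, where the intervals compared had median log2 ratios of 2.05 and 2.65 and so were themselves far above SH-SY5Y. Its H3K4me3 ratio stood at percentile 79.1 of 201 and 27 of 319.

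SH-EP had 2.06 times as many H3K4me3 peaks as SH-SY5Y. Covered length differed less, at 50.9 Mb in SH-EP and 38.3 Mb in SH-SY5Y. The peaks of SH-EP were narrower, with a median width of 412 bp against 877 bp, so peak number alone overstates the difference. One explanation of the higher number is that more weak peaks were called in SH-EP. Among peaks of at least 10-fold enrichment the ratio was 1.33, between the bounds set for and against it, and since fold scales differ between lists this stays open. A biological explanation is H3K4me3 at elements acetylated in SH-EP: the 24879 windows with H3K4me3 in SH-EP alone carried H3K27ac in 43.7% in SH-EP and 21.0% in the resistant line, a difference of 22.6 points. These windows were chosen for H3K4me3 in SH-EP and its absence from the other lines, so such a difference could arise under either explanation. The value does not decide between them, and a difference in depth is not excluded.

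The resistant line overlapped SH-EP more than its parent by H3K27ac. Unequal length of the lists was not needed for this order, since at equal covered length the Jaccard index was still higher with SH-EP by 0.139. This check was weak, because the deposited SH-EP list was already the shorter partner (66.5 Mb, against 71.1 Mb in SH-SY5Y). SH-EP chromatin mixed into the H3K27ac sample would bring the strongest SH-EP peaks along, yet 26.9% of 1873 such peaks absent from SH-SY5Y had no peak in the resistant line; a small admixture that left some peaks under the calling threshold is not ruled out by this value. An exchange of the SH-SY5Y H3K27ac label with another line was argued against by H3K4me3: windows with H3K4me3 in the resistant line and not SH-SY5Y carried H3K27ac 2.94 times as often in the list named resistant as in that named SH-SY5Y, and the like ratio for SH-EP was 4.08. A biological likeness of the lines named mesenchymal stays open and was not tested, and depth, culture and batch were not examined.

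By H3K27me3 the resistant line was nearer to SH-EP over all peaks and nearer to SH-SY5Y among strong ones. Unequal lists were argued against, since with strong peaks trimmed to equal covered length the Jaccard index with SH-EP minus that with SH-SY5Y was -0.192 at a fold of at least 4 (95% interval -0.224 to -0.160) and -0.114 at a −log10 q of at least 5 (-0.143 to -0.0848). For the strong peaks of the resistant line, a threshold acting on the partner list was argued against at 4-fold. Any SH-SY5Y peak covered 89.2% and any SH-EP peak 55.7% of that length, a ratio of 1.60 (1.42 to 1.78). In the other direction the shares lay closer. Any resistant-line peak covered 76.3% of the 4-fold length of SH-SY5Y and 71.3% of that of SH-EP. From that side a threshold on the resistant-line list may add to the gap in the Jaccard index. The threshold on the partner list stays open at a −log10 q of at least 5. There the ratio was 1.22 (1.07 to 1.36), and its interval spans the bound set against it. Between 3-fold and 4-fold the shares of resistant-line length were 58.5% and 60.6%. No biological explanation was tested, and shared background among weak calls was not examined.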
